A study of Arabidopsis thaliana with 42 samples.

How the data were processed

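RNA sequencing libraries from Arabidopsis thaliana were analysed from their deposited gene counts, 1 file per library and 42 in all. Per the labels, 24 libraries came from mesophyll protoplasts of soil-grown wild type (Col-0) in which 1 of the 9 NLP transcription factors was expressed transiently, or from control protoplasts. The other 18 came from whole seedlings of wild type, of the septuple mutant nlp2,4,5,6,7,8,9 and of chl1-5, a mutant of the nitrate transporter NRT1.1. The seedlings were 7 days old, had ammonium as their nitrogen source, and were treated over 20 min with KCl or KNO3 at 10 mM. The labels mark these groups K and N, and K was read as KCl and N as KNO3 from the treatment protocol.

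The authors deposited raw read counts per gene as whole numbers, per the file format without any normalisation. Per the submitters' processing notes, FastQC 0.11.5, TopHat2 2.1.1, featureCounts, HTSeq 0.6.1 and the genome build TAIR10 were used, with no role or order stated. The last 5 lines of each count file are totals in the form htseq-count writes (reads with no gene, ambiguous, not unique and others). They stayed out of library sizes and tests. Reads with no gene came to between 0.75 and 4.97% of the assigned reads in the protoplast libraries and between 0.65 and 5.72% in the seedling libraries. Alignments that were not unique came to between 6.4 and 71.7% and between 12.1 and 58.1%. Genes with near-identical copies, such as NRT2.1 and NRT2.2 or CAB1, CAB2 and CAB3, are uncertain for this reason, and so are overlapping and antisense genes, since the strand setting of the counting is not given in the sources used here. Each count file holds 37336 loci. Symbols were taken from a reference gene table of the assembly TAIR10.1, which paired 37051 loci with an entry and left 285 unpaired. That table was used for names and gene order alone.

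The authors also deposited 12 comparison tables, each with a log2 fold change and an adjusted p-value per gene. Per the file headers, their columns carry the names that DESeq2 writes, and the tool and the adjustment are not given in the sources used here. These tables were compared with the results obtained here, and those for NLP4 and NLP6 entered 1 test of an exchange of samples.

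Total gene counts per library lay between 5.6 and 27.7 M (megacounts) in protoplasts (median 12.8 M) and between 18.3 and 59.7 M in seedlings (median 30.6 M). A count of 0 in 1 library allows a level of up to 3 counts, which is 0.108 to 0.532 CPM (counts divided by the library total in M) in protoplasts and 0.05 to 0.164 CPM in seedlings. Reads are not independent molecules, so such limits cover counting error alone. Where all libraries of a group had 0 counts, a fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts over a group of a protoplast contrast, the ratio of CPM is given with the exact 95% Poisson interval of that count.

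Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation and the filterByExpr filter by group. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. All 18 seedling libraries were fitted together, with 6 groups of 3, 21229 genes and 12 residual degrees of freedom. The protoplast libraries were fitted together as well, with 12 groups of 2 per the labels, 19311 genes and 11 residual degrees of freedom. Each NLP was compared with the control the labels name for it. The 2 libraries of the control for NLP1, 2, 3, 5, 8 and 9 differed by about the sampling noise outside the NLP genes. Their chi-square statistic was 1.07 per gene over 15881 genes, and 1.01 over 15872 genes without the 9 NLP genes (p = 0.12), while every other replicate pair gave 3.73 or more. They were summed and counted as 1 sample, which leaves 23 libraries in the fit. That was decided after the counts were seen and departs from the design with 24 libraries, whose values are among the alternatives. The common biological coefficient of variation was 0.43 in seedlings and 0.16 in protoplasts. CPM values were scaled by TMM, except those of the label checks, which are counts over the library total, and are given as mean ± SD. Log2 fold changes are given ± SE, the SE being the size of the fold change divided by the root of its F statistic. A log2 fold change of a gene near 0 counts in 1 group depends on the prior count.

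The design, the groups, the alternatives and the rule for named genes were fixed before the data were examined. The rule took genes past the threshold with a group mean of at least 5 CPM and, in contrasts of 2 groups, no overlap between the libraries. In order of the log2 fold change, it took the 10 highest and 5 lowest of each nitrate response and interaction, the 4 highest and 2 lowest of each NLP without the expressed NLP itself, and the 5 highest and 5 lowest of each contrast between genotypes in K. Members of the gene lists may be named as well. There were 18 lists with 172 loci: nitrate transport, nitrate reduction and ammonium assimilation, reductant supply, nitrate regulators, cytokinin synthesis and response, the NLP family, ammonium transport, sulfate assimilation, phosphate starvation, touch, wounding and rapid stress, heat shock, hypoxia, the circadian clock, and markers of mesophyll and photosynthesis, guard cells, epidermis, vasculature and root. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 324 tests, and again with an estimated correlation. Of 68 list tests called, 4 held with an estimated correlation: reductant supply in wild type, in chl1-5 and in the septuple mutant against wild type, and nitrate regulators in wild type.

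Sets of genes were compared by one-sided Fisher's exact tests. Medians of sets have 95% intervals from 2000 bootstrap draws over genes. For NLPs with the same control, fold changes of unchanged groups were simulated 20 times against those control libraries, with all libraries and in the fit without 4 of them. The alternatives were DESeq2 1.42.0, size factors by the RLE method, no filter on low counts, the replicate number as a block, only the libraries of the groups compared, and each library left out in turn. After the data were seen, 2 more were added: the control pair as 2 samples, and a fit without 4 protoplast libraries whose NLP reads contradict their labels. In the latter fit, with 19288 genes and a common biological coefficient of variation of 0.09, the labels NLP4, 5, 6 and 8 rest on 1 library each, which is assumed to vary like the others. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

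The tests were tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For the nitrate response of wild type (20799 genes), 33% and 74% were called, with 4 unchanged genes called. For the septuple mutant against wild type (20774 genes) the shares were 6% and 43%, with 1 unchanged gene called. For NLP7 (18588 genes) they were 51% and 86%, with 8 unchanged genes called, and for NLP2 (18581 genes) 38% and 85%, with 4. The labels do not state that replicates came from separate cultures or plants, so p-values measure the spread between these samples, which may be technical. Samples of chl1-5 have a growth text of their own in the labels, so a batch and this genotype cannot be separated in contrasts of chl1-5 with the others.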

Results

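Messenger RNA was measured by sequencing in 42 Arabidopsis thaliana libraries, in an experiment on how plants sense nitrate through NRT1.1, a nitrate transporter, and the NLP (NIN-like protein) transcription factors. Mesophyll protoplasts are leaf cells without a cell wall that take up plasmid DNA. They made up 12 groups of 2 libraries, 1 group for each of NLP1 to NLP9 and 3 control groups (for NLP4 and 6, for NLP7, and for NLP1, 2, 3, 5, 8 and 9). Seedlings made up 6 groups of 3 libraries: wild type, the septuple mutant nlp2,4,5,6,7,8,9 and chl1-5, each after 20 min in 10 mM KCl (K) or KNO3 (N). Total gene counts were 5.6 to 27.7 M (megacounts) per protoplast library and 18.3 to 59.7 M per seedling library, with 19803 to 24251 and 19603 to 22880 genes detected. All adjusted p-values come from the edgeR quasi-likelihood test unless another test is named.

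The 9 NLP transcripts were examined first, as a check of the labels. In 14 of the 18 protoplast libraries with an expressed NLP, the labelled NLP was the highest of the 9, between 8600.58 CPM (NLP1 replicate 2) and 121199.78 CPM (NLP3 replicate 2). In 4 libraries it was not. The library labelled NLP5 replicate 2 held NLP8 at 41880.64 CPM and NLP5 at 434.44 CPM, while the library labelled NLP8 replicate 2 held NLP5 at 58390.77 CPM and NLP8 at 327.57 CPM. The library labelled NLP4 replicate 1 held NLP1 at 13201.74 CPM and NLP4 at 29.54 CPM, against 38.21 and 39.52 CPM of NLP4 in its controls. The library labelled NLP6 replicate 1 held NLP4 at 43118.41 CPM and NLP6 at 14.9 CPM. All groups were kept as labelled in the tests. The labels NLP4, NLP5, NLP6 and NLP8 each contain such a library, and the number of genes called in each protoplast contrast is therefore given again without the 4.

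**Figure D1:**
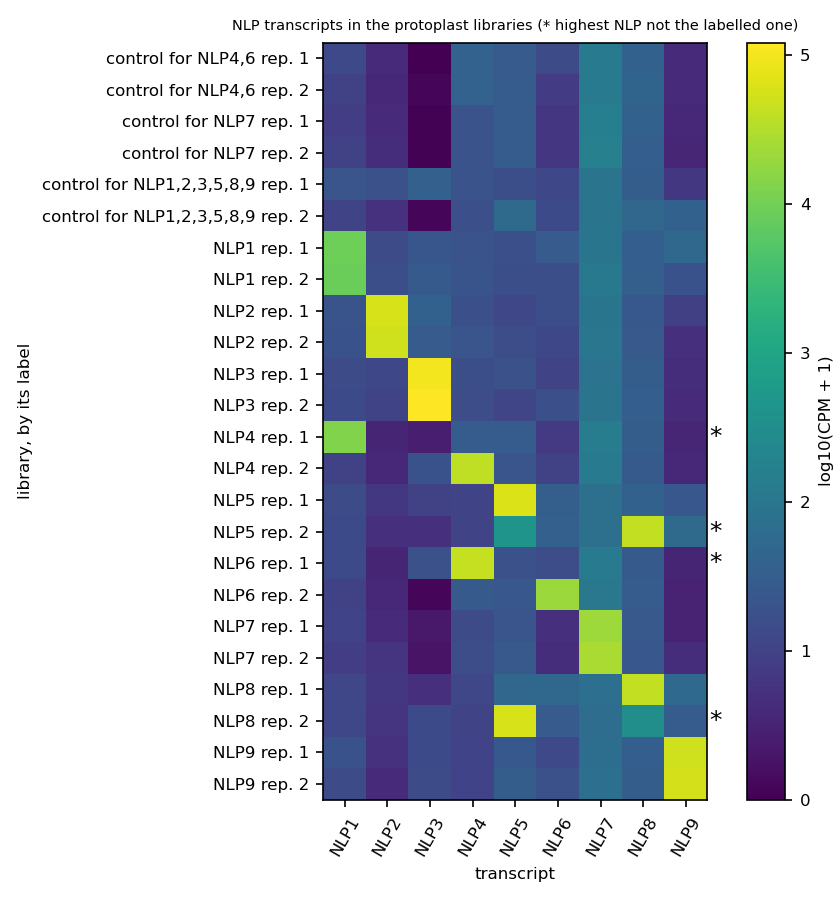
Level of the 9 NLP transcripts (columns) in each of the 24 protoplast libraries, named by their labels (vertical axis), as the log10 of CPM + 1 (colour). An asterisk marks the 4 libraries in which the highest NLP is not the labelled one.

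In seedlings, the transcripts of the mutated genes were examined in the same way. NLP8 had 0 counts in all 6 septuple mutant libraries. NLP2 lay between 0 and 3.83 CPM in the septuple mutant against 7.09 to 19.08 CPM in wild type, and NLP5 between 1.64 and 4.48 CPM against 5.39 to 11.91 CPM. NLP4, NLP6 and NLP7 still gave 20.16 to 35.76, 22.59 to 32.71 and 36.52 to 89.64 CPM in the septuple mutant, and NLP9 was low throughout (0.02 to 0.78 CPM against 0 to 2.42 CPM in wild type). Counts over the whole gene do not check an allele that leaves part of the transcript. NRT1.1 lay between 49.72 and 90.87 CPM in the 6 chl1-5 libraries, 488.7 to 916.52 CPM in wild type and 355.08 to 571.8 CPM in the septuple mutant.

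Which genes respond to nitrate within 20 min was asked first in wild type. Genes of nitrate reduction rose: NIR1, nitrite reductase, from 207 ± 47.3 to 1400 ± 81.4 CPM (SD, n = 3; log2 fold change 2.75 ± 0.23, adjusted p = 3.76e-08), NIA1, nitrate reductase, by 1.7 ± 0.22 (adjusted p = 2.52e-05) and NIA2 by 1.19 ± 0.22 (adjusted p = 0.00364). UPM1, which makes a precursor of the siroheme cofactor of NIR1, rose by 1.94 ± 0.20 (adjusted p = 9.43e-07). The transporter gene NRT2.1 rose by 1.82 ± 0.34 (adjusted p = 0.00462) and its partner NRT3.1 by 2.04 ± 0.24 (adjusted p = 9.06e-06), while NRT1.8, a transporter that unloads nitrate from the xylem, fell by 1.85 ± 0.42 on the log2 scale (adjusted p = 0.0317). NRT1.1 itself had a log2 fold change of 0.83 ± 0.23 (adjusted p = 0.097).

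In all, 154 of 21229 genes were called in wild type, 131 higher and 23 lower with nitrate. The 10 highest by the rule were AT3G07350 (10.1 ± 0.719 to 238 ± 41.1 CPM, log2 fold change 4.56 ± 0.29, adjusted p = 2.61e-10), BT2 (4.14 ± 0.42, adjusted p = 6.61e-07), AT5G65980 (3.86 ± 0.86, adjusted p = 0.0252), MAPKKK13 (3.60 ± 0.31, adjusted p = 5.29e-08), AT2G22200 (3.39 ± 0.81, adjusted p = 0.0433), BT1, the gibberellin synthesis gene GA3OX1, AT1G77400, AT2G48080 and IPT3, an enzyme of cytokinin synthesis (2.82 ± 0.30, adjusted p = 1.43e-06). BT1 and BT2 encode BTB and TAZ domain proteins. The lowest were AT3G50800 (fell by 1.99 ± 0.38, adjusted p = 0.00637) and the calmodulin-like gene CML37 (fell by 1.92 ± 0.45, adjusted p = 0.0383).

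By list, 6 of 10 measured genes of reductant supply rose and none fell (8 adjusted over the list alone; median log2 fold change 1.40, camera adjusted p = 7.96e-14). They were G6PD3 (2.7 ± 0.23, adjusted p = 5.29e-08) and G6PD2, glucose-6-phosphate dehydrogenases, PGD1 and PGD3 (2.36 ± 0.21, adjusted p = 9.04e-08) of the same pentose phosphate pathway, the ferredoxin FD3 (1.5, adjusted p = 0.000167) and its reductase RFNR2. Of 21 nitrate regulators 7 rose (12 adjusted over the list alone; median 1.02, adjusted p = 2.27e-17), among them the repressors LBD37 (175 to 907 CPM, log2 fold change 2.37 ± 0.25, adjusted p = 1.43e-06), LBD38 and LBD39 (2.73 ± 0.27, adjusted p = 3.68e-07) and HHO2 and HHO3. Of 14 genes of nitrate reduction and ammonium assimilation 5 rose (6 adjusted over the list alone; median 0.32, adjusted p = 1.72e-07, and adjusted p = 0.342 with an estimated correlation). Of 14 nitrate transport genes 2 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.53, adjusted p = 0.00235, and adjusted p = 0.461 with an estimated correlation). NLP3 was the member of the NLP family that rose, from 3.43 ± 1.82 to 20.3 ± 6.79 CPM (2.57 ± 0.42, adjusted p = 0.000963), and this list was not called (adjusted p = 0.868). Mesophyll and photosynthesis markers were higher as a list (2 of 8 rose, CAB2 and LHCB2.1, and 7 adjusted over the list alone; median 0.79, adjusted p = 1.67e-08, and adjusted p = 0.461 with an estimated correlation), and so were cytokinin genes (1 of 15, IPT3, and 2 adjusted over the list alone; adjusted p = 0.0113, and adjusted p = 0.466 with an estimated correlation).

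The remaining 11 lists were not called in wild type. Their medians and adjusted p-values were 0.68 and 0.226 for ammonium transport, 0.06 and 0.69 for sulfate assimilation, -0.34 and 0.865 for phosphate starvation, -0.43 and 0.0548 for touch, wounding and rapid stress, -0.46 and 0.455 for heat shock, -0.17 and 0.331 for hypoxia and -0.14 and 0.94 for the circadian clock. For markers they were -0.36 and 0.16 (guard cells), 0.18 and 0.226 (epidermis), 0.33 and 0.172 (vasculature) and 0.23 and 0.375 (root).

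DESeq2 called 497 genes in wild type. The edgeR count was 99 without K replicate 1, 100 without K replicate 3 and 82 without N replicate 2. AT5G65980 lost its call without K replicate 2 or 3 or N replicate 2 or 3 (adjusted p = 0.0808, 0.122, 0.089 and 0.0858), and AT2G22200 without any library except K replicate 2 (adjusted p between 0.077 and 0.214). NRT1.8 lost it without K replicate 2 or 3 or N replicate 1 or 3 (adjusted p = 0.0873, 0.0952, 0.109 and 0.134), CML37 without the same 4 (0.0934, 0.164, 0.0874 and 0.171), AT3G50800 without K replicate 1 (adjusted p = 0.0629) and HHO3 without N replicate 3 (adjusted p = 0.0729).

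Whether the nitrate response needs the NLPs was tested in the septuple mutant. No gene was called there by edgeR, 438 genes (2.06%, against 5% expected with no change) had an unadjusted p under 0.05, and DESeq2 called 4. NIR1 measured 37.5 ± 6.11 CPM in K and 66.7 ± 12.5 CPM in N (log2 fold change 0.83 ± 0.22, adjusted p = 1), AT3G07350 measured 2.93 and 3.91 CPM, MAPKKK13 5.41 and 5.31 CPM, and NRT2.1 2.35 and 2.03 CPM. The log2 fold changes of NIA1, G6PD3, BT1, BT2, LBD37 and LBD39 were -0.17, 0.12, -0.08, 0.57, 0.35 and 0.03. Mesophyll and photosynthesis markers were lower with nitrate as a list, with none of 8 genes called (median -0.40, adjusted p = 8.66e-06, and adjusted p = 0.499 with an estimated correlation), and so were vascular markers (median -0.43, adjusted p = 0.0234, and adjusted p = 0.554 with an estimated correlation). The lists of nitrate transport, nitrate reduction, reductant supply and nitrate regulators had medians of -0.21, 0.03, 0.08 and 0.15 (adjusted p = 0.47, 0.865, 0.742 and 0.16).

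Whether it needs NRT1.1 was tested in chl1-5, where 26 genes were called, 25 higher and 1 lower with nitrate. BT1 rose by 2.97 ± 0.33 (4.76 to 37.3 CPM, adjusted p = 1.07e-05), AT3G07350 by 2.82 ± 0.27 (22.2 to 157 CPM, adjusted p = 2.2e-06), MAPKKK13 by 2.80 ± 0.31 (adjusted p = 1.07e-05), BT2 by 2.75 ± 0.40 (adjusted p = 6e-04) and MAPKKK14 by 1.92 ± 0.23 (adjusted p = 3.2e-05). NIR1 rose from 335 ± 71.2 to 1210 ± 231 CPM (1.85 ± 0.22, adjusted p = 3.2e-05), NIA1 by 1.58 ± 0.22 (adjusted p = 0.000253), G6PD3 by 1.64 ± 0.23 (adjusted p = 0.000253) and UPM1 by 1.46 ± 0.20 (adjusted p = 0.000253). NRT2.1 had a log2 fold change of 0.99 (adjusted p = 0.518) and NRT3.1 of 1.04 (adjusted p = 0.0957). Of the lists, reductant supply (2 of 10 rose, 6 adjusted over the list alone; median 0.70, adjusted p = 4.43e-06), nitrate regulators (5 of 21, 9 adjusted over the list alone; adjusted p = 1.06e-10, and adjusted p = 0.0557 with an estimated correlation) and nitrate reduction and ammonium assimilation (4 of 14, and 4 adjusted over the list alone; adjusted p = 1.92e-05, and adjusted p = 0.461 with an estimated correlation) were higher. DESeq2 called 141 genes. The edgeR count was 46 without K replicate 2 and 15 without N replicate 2.

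The nitrate responses of the genotypes were then compared by interaction tests. For 59 genes the log2 fold change with nitrate was lower in the septuple mutant than in wild type, and for none higher. BT1 differed by -3.36 (adjusted p = 0.000144), IPT3 by -3.11 ± 0.42 (adjusted p = 0.000144), LBD39 by -2.7 (adjusted p = 0.000144), G6PD3 by -2.58 (adjusted p = 6.53e-05), NRT3.1 by -2.24 (adjusted p = 0.000679), PGD3 by -2.19 (adjusted p = 0.000144), NIR1 by -1.92 ± 0.30 (adjusted p = 0.00136) and NIA1 by -1.87 (adjusted p = 0.00173) on the log2 scale. The 5 lowest by the rule were ATCG00920 (-13.78 ± 2.53, adjusted p = 0.0089), AT2G48080 (-4.51 ± 0.65, adjusted p = 0.000345), AT3G07350 (-4.18 ± 0.38, adjusted p = 8.34e-07), MAPKKK13 (-3.63 ± 0.42, adjusted p = 4.72e-05) and ATMG01390 (-3.59 ± 0.79, adjusted p = 0.0454). ATCG00920 and ATMG01390 are organellar loci that varied widely between replicates (27.1 ± 28.2 and 2310 ± 2070 CPM in wild type with nitrate). Wild-type N replicate 1 was the highest of these, at 58.2 and 4690 CPM. It also had the highest share of alignments that were not unique among the seedling libraries, 58.1%. The means of both loci fell with nitrate in the septuple mutant, from 2.92 ± 4.69 to 0.0111 ± 0.0192 CPM and from 793 ± 663 to 316 ± 88.5 CPM. Reductant supply differed as a list (4 of 10 genes lower, 7 adjusted over the list alone; median -1.27, adjusted p = 2.58e-09), as did nitrate regulators (5 of 21, 10 adjusted over the list alone; adjusted p = 2.35e-09, and adjusted p = 0.0699 with an estimated correlation), nitrate reduction (4 of 14, 5 adjusted over the list alone; adjusted p = 3.2e-05, and adjusted p = 0.461 with an estimated correlation) and mesophyll markers (1 of 8, LHCB2.1, and 8 adjusted over the list alone; adjusted p = 4.34e-10, and adjusted p = 0.38 with an estimated correlation).

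DESeq2 called 484 genes in this interaction. The edgeR count was 163 without wild-type K replicate 2, 35 without wild-type K replicate 3 and 39 without wild-type N replicate 3, and it was 34, 38, 32 and 34 without septuple mutant K replicate 1 and N replicates 1, 2 and 3. ATCG00920 lost its call without septuple mutant K replicate 1 (adjusted p = 0.0836). ATMG01390 lost it without wild-type K replicates 1 or 3 or N replicate 1, or septuple mutant K replicate 1 or N replicate 1, 2 or 3 (adjusted p between 0.087 and 0.245).

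Between chl1-5 and wild type, 2 genes were called by edgeR and 35 by DESeq2. AT5G44380, which encodes a berberine bridge enzyme-like protein, went from 72.1 ± 16.3 CPM in K to 33.7 ± 3.89 CPM in N in wild type and from 22.3 ± 6.45 to 39.9 ± 9.45 CPM in chl1-5 (difference 1.93 ± 0.32, adjusted p = 0.0213). The other gene, the ribonuclease RNS3 (11.31, adjusted p = 0.0213), was outside the rule and was chosen after its values were seen. It had 0 counts in all 3 chl1-5 libraries in K and 2.97 ± 1.8 CPM in N, so this difference depends on the prior count. No gene was called without wild-type K replicate 2, wild-type N replicate 1 or 3, chl1-5 K replicate 1 or 3 or chl1-5 N replicate 3, 1 without wild-type K replicate 1, and 21 without chl1-5 K replicate 2. AT5G44380 also lost its call without wild-type K replicate 1 or chl1-5 N replicate 2 (adjusted p = 0.0852 and 0.0724). As a list, reductant supply rose less in chl1-5 (none of 10 called, 5 adjusted over the list alone; median -0.66, adjusted p = 7.58e-05, and adjusted p = 0.0699 with an estimated correlation).

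Between the septuple mutant and chl1-5, the responses of 7 genes were called, all with a lower log2 fold change in the septuple mutant. Among them were BT1 (-3.05 ± 0.44, adjusted p = 0.00395), MAPKKK13 (-2.83 ± 0.42, adjusted p = 0.00395), AT3G07350 (-2.44 ± 0.38, adjusted p = 0.00538), MAPKKK14 (-1.91 ± 0.32, adjusted p = 0.0122), NIA1 (-1.75, adjusted p = 0.0171) and RNS3 (-10.02 ± 1.82, adjusted p = 0.0435), which had 0 counts in chl1-5 in K, so that its value depends on the prior count. DESeq2 called 32. The edgeR count was 3 without septuple mutant N replicate 1, chl1-5 K replicate 3 or chl1-5 N replicate 3, and 4 without septuple mutant K replicate 1 or 2 or N replicate 2. BT1, MAPKKK13 and AT3G07350 kept their calls without each of the 12 libraries. MAPKKK14 lost its call without septuple mutant K replicate 2 or N replicate 1, or chl1-5 K replicate 3 or N replicate 3 (adjusted p = 0.0737, 0.0699, 0.0559 and 0.0611). RNS3 lost it without each library but chl1-5 N replicate 1 (adjusted p between 0.0664 and 0.162). NIA1 lost it without septuple mutant K replicate 1 or N replicate 1 or 2, chl1-5 K replicate 1, 2 or 3 or chl1-5 N replicate 3 (adjusted p between 0.0559 and 0.114).

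**Figure D2:**
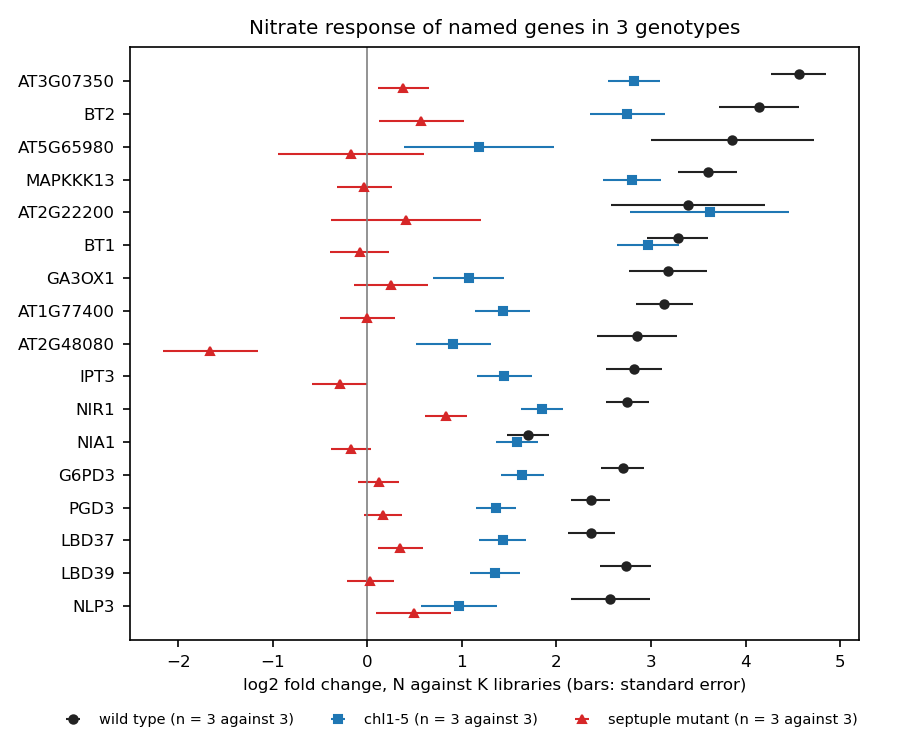
Log2 fold change, N against K libraries (horizontal axis; bars, SE; n = 3 against 3), of 17 genes (vertical axis) in wild type, chl1-5 and the septuple mutant. For NIR1 it was 2.75 ± 0.23 in wild type, 1.85 ± 0.22 in chl1-5 and 0.83 ± 0.22 in the septuple mutant.

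As a set, the 116 genes that rose 2-fold or more in wild type had a median log2 fold change of 1.54 there, 0 in the septuple mutant, where 58 had the same sign and 0 were called, and 0.79 in chl1-5, where 109 had the same sign and 19 were called. This set was chosen on the wild-type libraries, which inflates the first value. The 26 genes called in chl1-5, 25 of them rising, were therefore examined in the other genotypes. Their median was 2.28 in wild type (95% interval over genes 1.4 to 2.73) and 0.05 in the septuple mutant (-0.07 to 0.17), with 14 of the 26 in the same and 12 in the opposite direction. Without wild-type K replicate 2 the median in wild type was 2.45. The set holds ELP (3.19 in chl1-5), a gene 2 places from NRT1.1 at 1.77 to 40.2 CPM in chl1-5 in N against 1780 CPM in wild type, and without it the medians over 25 genes were 2.33 in wild type and 0.08 in the septuple mutant.

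The mutants also differed from wild type without nitrate. In K, 299 genes were higher and 178 lower in the septuple mutant. The defence genes PR1 and BGL2 were higher, from 0.166 to 11.7 CPM (6.03 ± 1.13, adjusted p = 0.00256) and from 0.200 to 7.96 CPM (5.34 ± 1.19, adjusted p = 0.0116). NRT2.1 was lower at 2.35 ± 0.908 against 40.7 ± 23.9 CPM (-4.08 ± 0.38, adjusted p = 2.77e-07), as were NIR1 (-2.46 ± 0.22, adjusted p = 1.76e-07), LBD37 (-2.18, adjusted p = 7.22e-06), BT2 (-2.77) and ARR7, a cytokinin response regulator (-2.64 ± 0.40, adjusted p = 0.000209). NLP8 was at least 236-fold lower (adjusted p = 5.33e-06), and AT3G11210 (-6.00 ± 0.53, adjusted p = 1.05e-07), AT4G32950 (-5.77 ± 0.48, adjusted p = 6.65e-08), NLP2 (-4.56 ± 0.66, adjusted p = 0.000128) and NLP5 (-2.0, adjusted p = 0.0102) fell as well. Of the 21 nitrate regulators 5 were lower (8 lower and 1 higher adjusted over the list alone; adjusted p = 0.000993, and adjusted p = 0.461 with an estimated correlation), and of the 14 genes of nitrate reduction 4 (6 and 1; adjusted p = 0.011, and adjusted p = 0.59 with an estimated correlation). DESeq2 called 810 genes, and edgeR 246 without wild-type K replicate 3, and 296 and 291 without septuple mutant K replicates 1 and 2. PR1 lost its call without septuple mutant K replicate 2 (adjusted p = 0.0605), BGL2 without wild-type K replicate 1 or 3 or septuple mutant K replicate 1 (0.053, 0.052 and 0.0527), and NLP5 without septuple mutant K replicate 1 (0.0803).

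In chl1-5 in K, 563 genes were higher and 600 lower than in wild type. NRT1.1 fell to 69.2 ± 9.78 from 490 ± 121 CPM (-2.82 ± 0.24, adjusted p = 1.07e-07) and ELP, an extensin-like gene, to 1.79 ± 0.516 from 923 ± 309 CPM (-9.01 ± 0.74, adjusted p = 6.98e-08). GSTU12, a glutathione transferase, fell by 4.63 ± 0.77 on the log2 scale (adjusted p = 0.00282). AT2G13175 had 0 counts in wild type in K and 9.78 ± 5.25 CPM in chl1-5, at least 485-fold higher (adjusted p = 6.63e-05), and the ethylene response factor ERF104 rose by 1.98 ± 0.27 (adjusted p = 3e-04). Of 8 mesophyll and photosynthesis markers 6 were higher (7 adjusted over the list alone; median 1.1, adjusted p = 1.67e-08, and adjusted p = 0.461 with an estimated correlation), for example LHCB2.1 (1.63 ± 0.23, adjusted p = 0.000371) and LHCA1 (1.30 ± 0.22, adjusted p = 0.00343). Lists of ammonium transport (AMT1;3 of 4 genes rose, adjusted p = 0.0239, and adjusted p = 0.554 with an estimated correlation) and root markers (1 of 6, adjusted p = 0.0447, and adjusted p = 0.466 with an estimated correlation) were higher too. DESeq2 called 2574 genes. The edgeR count was 199, 2111 and 152 without wild-type K replicates 1, 2 and 3, and 228, 2537 and 193 without chl1-5 K replicates 1, 2 and 3. With only the libraries of the 2 groups compared it was 41, and a batch of chl1-5 samples cannot be separated from this genotype.

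Which genes each NLP induces was asked in protoplasts. With NLP7, 1246 genes were higher and 613 lower than in its control. NIR1 rose from 445 to 2490 CPM (2.48 ± 0.55, adjusted p = 0.0102) and NIA1 by 1.44 ± 0.42 (adjusted p = 0.0397). The nitrate-responsive repressor HHO1, with 3 counts in its control, rose 516-fold (95% counting interval 176 to 2500, adjusted p = 0.000476), the asparagine synthetase ASN2 by 4.09 (adjusted p = 0.000873) and the GATA factor GNC by 4.35 (adjusted p = 0.000578). The highest by the rule were MBD3, at least 469-fold (adjusted p = 0.00642), QWRF7 from 0.122 to 553 ± 42.2 CPM (11.91 ± 2.11, adjusted p = 0.00214), AT4G34760, at least 372-fold (adjusted p = 0.000463), and ZPR4, at least 333-fold (adjusted p = 8e-06). LHCB2.1 rose by 1.87 ± 0.17 (adjusted p = 3.71e-06). Nitrate regulators were higher as a list (5 of 20 called; adjusted p = 0.0238, and adjusted p = 0.805 with an estimated correlation). The count was 664 and 843 without control replicates 1 and 2, 773 and 968 without NLP7 replicates 1 and 2, and 4554 in the fit without the 4 mismatched libraries, none of which is in this contrast. NIR1 and MBD3 lost their calls without control replicate 1 (adjusted p = 0.0956 and 0.0504) or 2 (0.0761 and 0.074), and NIA1 without any 1 of the 4 libraries (adjusted p between 0.119 and 0.225). NIR1 was 2.51 ± 0.08 (adjusted p = 2.6e-17) without the 4 mismatched libraries.

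With NLP2, 1277 genes were higher and 1489 lower, and with NLP9, 1505 were higher and 2219 lower. The control for NLP1, 2, 3, 5, 8 and 9 entered all its tests as 1 sample, so their p-values do not measure its own spread. Leaving out 1 of its libraries mainly lowers its depth. NRT2.1 had 0 counts in this control. It rose to 153 ± 7.87 CPM with NLP2, at least 1010-fold (adjusted p = 0.023), and to 76.4 ± 10.4 CPM with NLP9, at least 504-fold (adjusted p = 0.0291). MBD3 rose at least 885-fold and 444-fold (adjusted p = 0.00932 and 0.0109) and QWRF7 at least 680-fold and 357-fold (adjusted p = 0.0324 and 0.0408). NIR1 rose by 3.11 ± 0.76 with NLP2 (adjusted p = 0.0137) and 3.41 ± 0.77 with NLP9 (adjusted p = 0.00646), LBD38 by 3.69 ± 0.83 and 3.1 ± 0.81 (adjusted p = 0.00924 and 0.0141) and FD3 by 2.86 ± 0.66 and 3.67 ± 0.69 (adjusted p = 0.0102 and 0.00199). NRT1.8 fell by 2.95 ± 0.35 with NLP9 (adjusted p = 8.91e-05). Of 10 genes of reductant supply 4 rose and 1 fell with NLP2 and 5 rose and 1 fell with NLP9 (camera adjusted p = 0.007 and 0.00455, and adjusted p = 0.666 and 0.621 with an estimated correlation). The counts were 1290 and 1398 without NLP2 replicates 1 and 2, 2295 and 2064 without NLP9 replicates 1 and 2, and 5983 and 6382 without the 4 mismatched libraries. NRT2.1 lost its call without NLP2 replicate 1 or 2 (adjusted p = 0.0509 and 0.0508), and with NLP9 without control replicate 2 or NLP9 replicate 1 or 2 (0.056, 0.0581 and 0.0554), and QWRF7 lost it without any 1 library (adjusted p between 0.0517 and 0.0843). In the last of these fits NRT2.1 was 14.06 ± 0.40 with NLP2 (adjusted p = 7.6e-18), a fitted value that depends on the prior count.

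With NLP1, 188 genes were higher and 118 lower, and with NLP3, 227 were higher and 311 lower. TSO2, a small subunit of ribonucleotide reductase, rose from 12.1 to 253 ± 9.89 CPM with NLP1 (4.38 ± 0.20, adjusted p = 1.02e-08) and to 182 ± 7.52 CPM with NLP3 (3.91 ± 0.20, adjusted p = 3.94e-08). GR1 (AT3G52115) rose by 5.57 ± 0.40 and 4.51 ± 0.39 (adjusted p = 1.43e-06 and 2.41e-05), AT3G27630, with 1 count in the control, 143-fold with NLP1 (95% counting interval 25.7 to 5660, adjusted p = 1.6e-05) and the mitotic cyclin CYCB1;1 by 3.37 ± 0.31 with NLP3 (adjusted p = 5.11e-05). These genes were not specific to NLP1 and NLP3: TSO2 also lay at 103 ± 3.56 CPM with NLP2, 135 ± 12.8 with NLP9, and 158 ± 19.5 and 160 ± 8.81 under the labels NLP5 and NLP8, each of which holds 1 library with either NLP. The control for NLP7 held it at 526 ± 7.23 CPM and CYCB1;1 at 77.8 ± 10 CPM, so the low level in the control for NLP1 and NLP3 enters each rise. NRT1.8 fell by 2.06 ± 0.33 with NLP1 (adjusted p = 0.00505). NIR1 was 2.34 ± 0.72 with NLP1 (adjusted p = 0.114) and 2.02 ± 0.71 with NLP3 (adjusted p = 0.141), and NIA1 was 0.08 ± 0.50 and -0.33 ± 0.49. The counts were 61 and 63 without NLP1 replicates 1 and 2, 104 and 120 without NLP3 replicates 1 and 2, and 2918 and 3117 without the 4 mismatched libraries. In that fit NIR1 rose with both (2.32 ± 0.10 and 2.01 ± 0.10, adjusted p = 7.52e-14 and 1.11e-12), as did G6PD3 (4.90 ± 0.16 and 3.72 ± 0.16). NRT1.8 lost its call without NLP1 replicate 1 (adjusted p = 0.0576). DESeq2 called 692 genes with NLP1 and 901 with NLP3.

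Under the label NLP4, 338 genes were higher and 331 lower, and under the label NLP6, 390 were higher and 393 lower. AT3G27630 had 0 counts in both control libraries. It was at least 31.5-fold higher under the label NLP4 (7.14 ± 0.233 CPM, adjusted p = 8.6e-06) and at least 36.5-fold higher under the label NLP6 (8.28 ± 1.73 CPM, adjusted p = 7.88e-06). The control for NLP7 held it at 23.9 and 19.7 CPM, so the low level in the control for NLP4 and 6 enters both rises. NIR1 was higher by 3.64 ± 0.58 and 3.68 ± 0.58 (adjusted p = 0.0039 and 0.00414), G6PD3 by 6.51 ± 1.54 in both (adjusted p = 0.0342 and 0.0307) and HHO1 at least 160-fold under the label NLP6 (adjusted p = 0.00851). G6PD3 lay at 904 CPM in NLP4 replicate 2 and 910 CPM in the library labelled NLP6 replicate 1, which both hold NLP4. In the other library of the labels NLP4 and NLP6 it lay at 71.1 and 68.9 CPM. BXL3 was lower under both (-4.37 ± 0.93 and -4.74 ± 1.01, adjusted p = 0.0216 and 0.0185), against a control mean of 37.4 ± 48.8 CPM. Reductant supply (5 and 6 of 10 genes higher, adjusted p = 0.000257 and 0.00387, and adjusted p = 0.555 and 0.617 with an estimated correlation) and nitrate regulators (2 and 5 of 20, adjusted p = 0.00531 and 0.000126, and adjusted p = 0.711 and 0.617 with an estimated correlation) were higher as lists. For these labels the count was 65 and 56 without control replicate 1 and 138 and 122 without control replicate 2. It was 2642 and 118 without NLP4 replicates 1 and 2, and 194 and 1892 without NLP6 replicates 1 and 2, and DESeq2 called 1321 and 1466. With only the libraries of the groups compared it was 6 and 132. Without control replicate 1 or 2 the adjusted p of NIR1 was 0.085 and 0.0542 for the label NLP4 and 0.0782 and 0.0564 for the label NLP6, and that of HHO1 for the latter was 0.104 and 0.0663. G6PD3 lost its call without either control or without NLP4 replicate 2 or NLP6 replicate 1 (adjusted p between 0.188 and 0.298), and BXL3 without control replicate 1, NLP4 replicate 2 or NLP6 replicate 1 or 2 (adjusted p between 0.0527 and 0.669). In the fit without the 4 mismatched libraries 4672 and 1599 genes were called, and NIR1 was 4.26 ± 0.09 with NLP4 and 2.52 ± 0.09 with NLP6 (adjusted p = 1.48e-20 and 7.35e-16), each from 1 library. There 8 of the 10 genes of reductant supply were higher and 1 lower with each (adjusted p = 0.0492 for both with an estimated correlation), and 12 and 11 of the 20 regulators were higher (0.0276 for both).

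Under the labels NLP5 and NLP8, 554 and 552 genes were higher and 1492 and 1554 lower. AT4G03500, with 1 count in the control, was 435-fold and 592-fold higher (95% counting intervals 78 to 17200 and 106 to 23400, adjusted p = 0.0366 and 0.0328). It lay at 40.6 CPM in NLP5 replicate 1 and 43.9 CPM in the library labelled NLP8 replicate 2, which both hold NLP5. In NLP8 replicate 1 and the library labelled NLP5 replicate 2, which hold NLP8, it lay at 4.36 and 4.26 CPM. Each of these folds thus mixes both NLPs. CYP707A2, an enzyme that breaks down abscisic acid, with 2 counts in the control, was 379-fold and 425-fold higher (105 to 3130 and 118 to 3510, adjusted p = 0.0442 and 0.042). On the log2 scale AT2G48080 rose by 7.78 ± 1.76 and 7.98 ± 1.76 (adjusted p = 0.0109 and 0.00919) and NIR1 by 3.48 ± 0.78 and 3.51 ± 0.78 (adjusted p = 0.0101 and 0.00928). AT1G52000 fell by 3.25 ± 0.48 and 3.15 ± 0.47 (adjusted p = 0.000735 and 0.000791). Reductant supply was higher as a list (4 of 10 genes each; adjusted p = 0.00106 and 0.000932, and adjusted p = 0.56 and 0.555 with an estimated correlation). The count was 829 without NLP5 replicate 2 and 896 without NLP8 replicate 1. With only the libraries of the groups compared edgeR called 188 and 0 genes, against 5010 and 5037 at an unadjusted p under 0.05 and 2369 and 2393 by DESeq2 with all libraries. AT4G03500 lost its calls without control replicate 1 or 2, NLP5 replicate 1 or NLP8 replicate 2 (adjusted p between 0.0514 and 0.131) and CYP707A2 without any 1 library (adjusted p between 0.0631 and 0.0768). Without the 4 mismatched libraries 3509 genes were called for NLP5 and 4783 for NLP8, and NIR1 was 3.90 ± 0.12 and 2.87 ± 0.11 (adjusted p = 2.8e-17 and 6.97e-15), each from 1 library.

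Between the libraries labelled NLP4 and NLP6, edgeR called 0 genes, 1137 (5.89%, against 5% expected with no change) had an unadjusted p under 0.05 and DESeq2 called 5. Each of these labels holds a library with NLP4 as its highest NLP, so the low counts do not show that NLP4 and NLP6 act alike. Without the 4 mismatched libraries the labels NLP4 and NLP6 rest on 1 library each. There the 10 genes of reductant supply had a median log2 fold change of 2.36 with NLP4 against NLP6, which is a difference between single libraries. Among NLP1, 2, 3, 5, 8 and 9, a joint test found 3633 genes that differed, 2316 without NLP1 replicate 2, 2417 without NLP9 replicate 2 and 7922 without the 4 mismatched libraries.

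How far the NLP effects in protoplasts cover the nitrate response of seedlings was tested with the genes that rose 2-fold or more in wild type. Of the 111 measured in protoplasts, 40 were higher with NLP2 (36.04% against 6.34% of other genes; one-sided Fisher's exact test, adjusted p = 1.66e-19), 39 with NLP9 (35.14% against 7.68%, adjusted p = 5.69e-16) and 34 with NLP7 (30.63% against 6.23%, adjusted p = 9.08e-15). With NLP1 it was 1 gene (0.9% against 1.03%, adjusted p = 0.682) and with NLP3 4 of 110 (3.64% against 1.22%, adjusted p = 0.0535). The median log2 fold change of these genes was 0.8 with NLP1 and 0.59 with NLP3, so the low counts do not show that they were unchanged. The calls use a spread estimated over all groups, those with the 4 mismatched libraries included. The Fisher tests treat genes as independent, which genes that respond together are not, so their p-values may be too small. Expression level was not matched between the set and the other genes. Under the labels NLP4, 5, 6 and 8 the number of higher genes was 28, 21, 31 and 23. In the fit with all libraries, none of the 111 genes was called higher with all 9 labels, and 50 were called with none. Neither of these 2 values held without the 4 mismatched libraries. They therefore do not show that no gene responds to every NLP. Without the 4 mismatched libraries the counts of higher genes for NLP1, NLP2, NLP3, NLP7 and NLP9 were 53, 83, 46, 71 and 73 (adjusted p between 5.41e-46 and 5.04e-23). There 5, 6, 12, 4 and 8 of the nitrate-induced genes were lower with these NLPs. With NLP4, NLP5, NLP6 and NLP8, from 1 library each, the median log2 fold change of the set was 1.52, 1.62, 0.71 and 0.96. With NLP9 the count was 26 to 32 without each of its libraries, but for the other NLPs it moved by over 1.5 times with 1 library left out. For the label NLP4 they were 0, 0, 52 and 2 without control replicates 1 and 2 and NLP4 replicates 1 and 2, and for the label NLP6 0, 1, 5 and 48 without controls 1 and 2 and NLP6 replicates 1 and 2. For NLP2 they were 19 and 17 without NLP2 replicates 1 and 2, for NLP7 17 and 16 without control replicates 1 and 2, for NLP5 13 without NLP5 replicate 1 and for NLP8 13 without NLP8 replicate 2. For NLP1 and NLP3 they were 0 without either NLP library, and 2 and 4 without control replicate 1, the latter past the threshold.

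**Figure D3:**
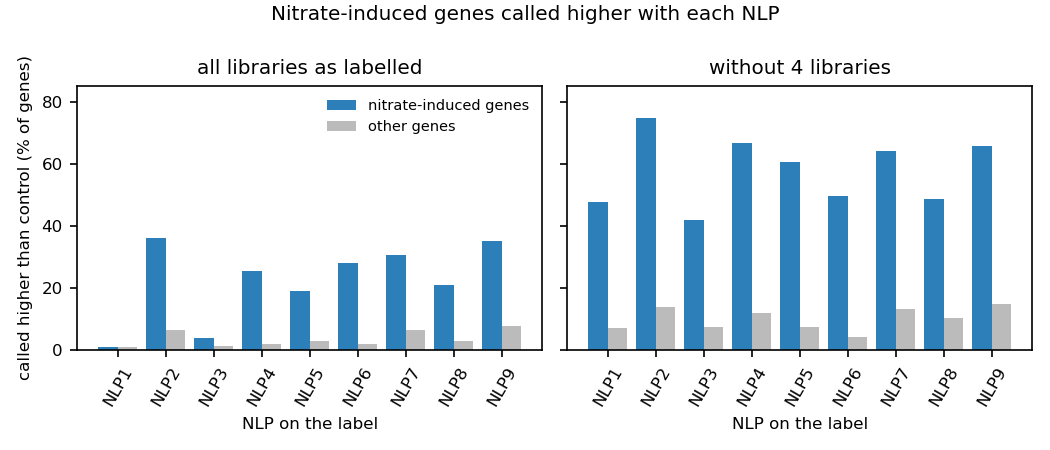
Share of genes higher than the control (vertical axis, percent) with each labelled NLP (horizontal axis), for the nitrate-induced genes of wild-type seedlings (blue) and the other genes (grey), with all libraries (left) and without the 4 mismatched ones (right). The share of nitrate-induced genes ran from 0.9% (NLP1) to 36.04% (NLP2) with all libraries and from 41.82% (NLP3) to 74.77% (NLP2) without the 4.

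Across the 145 genes called in wild-type seedlings and tested in protoplasts, fold changes with nitrate and with an NLP correlated with Pearson's r between 0.25 (NLP3) and 0.49 (the label NLP8) and Spearman's rho between 0.38 (NLP3) and 0.68 (the label NLP6). In the fit without the 4 mismatched libraries the highest were 0.48 and 0.67, both with NLP5 from 1 library. NLP8 then had 0.44 and 0.57, and NLP6 0.42 and 0.63. Across all 18044 genes r lay between 0.04 and 0.14. These are correlations across genes, which are not independent replicates. Between NLPs, 16 pairs that share control libraries had r between 0.68 and 0.94 (median 0.79), against averages of 0.54 to 0.69 per pair, and at most 0.71, for unchanged groups simulated with those controls. For 1 pair, NLP1 with NLP9, the observed 0.69 was under its highest simulated value of 0.7. The covariance of the 16 pairs was 0.68 to 1.7 against 0.26 to 0.27 simulated. The simulation drew each gene independently around the control mean, so it holds no offset of a whole control sample. An excess over the simulated values cannot be told from such an offset. The highest r, 0.94, was that of the labels NLP5 and NLP8, and each of these holds 1 library with the other's NLP. The 20 pairs without shared controls had r between 0.21 and 0.62 (median 0.51). Without the 4 mismatched libraries the 16 pairs had r between 0.54 and 0.86 (median 0.69), against simulated averages of 0.4 to 0.67 and at most 0.69 in that fit, and the 20 pairs between 0.17 and 0.61 (median 0.38). NLP4 with NLP6 was then 0.54 (simulated at most 0.42) and NLP5 with NLP8 0.68 (at most 0.46), each from 1 library per label. NLP1 with NLP9 and NLP3 with NLP9, both 0.69, did not exceed their highest simulated value of 0.69. NLP2 with NLP6, without a shared control, went from 0.54 to 0.24.

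The authors' deposited tables were compared with these results. In the authors' deposited tables for nitrate, the genes with an adjusted p under 0.05 numbered 736 in wild type, 4 in the septuple mutant and 33 in chl1-5, and of the 154, 0 and 26 genes called here 150, 0 and 21 were among them. Fold changes in the authors' deposited tables and here correlated across genes with r = 0.976, 0.99 and 0.988. For NLP7 the authors' deposited table called 2667 genes, 1507 of them among the 1859 called here (r = 0.997). For NLP1, 2, 3, 4, 5, 6, 8 and 9 the authors' deposited tables called 3910, 6264, 4087, 2586, 5112, 385, 6178 and 6714 genes. Of the 306, 2766, 538, 669, 2046, 783, 2106 and 3724 called here, 304, 2744, 537, 479, 1966, 255, 2064 and 3691 were among them. The authors' deposited tables correlated less with the results here for the labels NLP4 (r = 0.92), NLP5 (0.9), NLP8 (0.922) and NLP6 (0.744).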

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

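The 2 tests of an exchange between NLP4 and NLP6, of mixing, and of spread and depth in the septuple mutant were chosen after the results were seen, and the splits of the interactions were raised from 40 to 100 after the first 40 had been seen. The other tests were set before.

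The responses to nitrate differed between genotypes by tests of the difference itself. For the septuple mutant against wild type 59 genes were called, and the 5 lowest by the rule were ATCG00920 (-13.78), AT2G48080 (-4.51), AT3G07350 (-4.18), MAPKKK13 (-3.63) and ATMG01390 (-3.59). ATCG00920 lost its call without septuple mutant K replicate 1 (adjusted p = 0.0836). ATMG01390 lost it without wild-type K replicate 1 or 3 or N replicate 1, or septuple mutant K replicate 1 or N replicate 1, 2 or 3 (adjusted p between 0.087 and 0.245). The count was 163 without wild-type K replicate 2, and 35, 39, 34, 38, 32 and 34 without wild-type K replicate 3 and N replicate 3 and septuple mutant K replicate 1 and N replicates 1, 2 and 3. As many genes as 59 were called in 5 of 100 splits of these libraries, the real one included, and the highest other split called 1190 with 3 N and 1 K libraries exchanged. An unequal exchange of N and K libraries puts the difference between genotypes into the contrast, so these splits show a structure of the samples and do not tell whether chance can be excluded.

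For the response of chl1-5 against wild type 2 genes were called, AT5G44380 (1.93) by the rule and RNS3 outside it, the latter chosen after its values were seen. No gene was called without wild-type K replicate 2, wild-type N replicate 1 or 3, chl1-5 K replicate 1 or 3 or chl1-5 N replicate 3, 1 without wild-type K replicate 1, and 21 without chl1-5 K replicate 2. AT5G44380 also lost its call without wild-type K replicate 1 (adjusted p = 0.0852) or chl1-5 N replicate 2 (adjusted p = 0.0724). As many genes were called in 11 of 100 splits, with 2248 in the highest other, in which 3 N and 0 K libraries were exchanged, so for the same reason the count of splits leaves chance undecided.

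For the septuple mutant against chl1-5 7 genes were called, among them RNS3 (-10.02), BT1 (-3.05), MAPKKK13 (-2.83), AT3G07350 (-2.44) and MAPKKK14 (-1.91). RNS3 kept its call without chl1-5 N replicate 1 and lost it without each of the other 11 libraries (adjusted p between 0.0664 and 0.162). MAPKKK14 lost its call without septuple mutant K replicate 2 or N replicate 1, or chl1-5 K replicate 3 or N replicate 3 (adjusted p = 0.0737, 0.0699, 0.0559 and 0.0611). The count was 3 without septuple mutant N replicate 1 or chl1-5 K or N replicate 3, and 4 without septuple mutant K replicate 1 or 2 or N replicate 2. As many as 7 were called in 5 of 100 splits, with 5054 in the highest other, in which 0 N and 2 K libraries were exchanged, and this count of splits again leaves chance undecided.

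For the contrasts of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split and the highest other called 154 and 38 genes for nitrate in wild type (1 of 10 splits as large), 0 and 0 in the septuple mutant (10 of 10), and 26 and 47 in chl1-5 (2 of 10). They called 477 and 0 for the septuple mutant in K and 1163 and 6 for chl1-5 in K (1 of 10 each). The 0 genes of edgeR in the septuple mutant stand beside 438 at an unadjusted p under 0.05 (2.06%, against 5% expected with no change) and 4 by DESeq2.

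In 4 protoplast libraries the highest NLP was not the labelled one. An exchange of the libraries labelled NLP5 replicate 2 and NLP8 replicate 2 is a candidate explanation. With the NLP genes left out, each had a higher r with replicate 1 of the other label (0.961 with NLP8 against 0.828 with NLP5, and 0.965 with NLP5 against 0.827 with NLP8; smaller difference 0.133). For the libraries labelled NLP4 replicate 1 and NLP6 replicate 1 an exchange with each holding the plasmid of the other label is excluded, since the former held 6.44 CPM of NLP6. An exchange in which the NLP6 sample held NLP1 remains open. The authors' deposited table for NLP6 has NLP1 at 9.33 and that for NLP4 has it at 0.13, but this value prompted the test, and it shows which library was filed under NLP6, not what the library is. With the NLP genes left out, the library labelled NLP6 replicate 1 had r = 0.959 with NLP4 replicate 2 and 0.703 with NLP6 replicate 2. That labelled NLP4 replicate 1 had 0.457 with NLP6 replicate 2, lower than with NLP4 replicate 2 (0.595) or NLP1 replicate 2 (0.598). Reads of another sample mixed into a correctly labelled library are excluded as the source of the mismatch. The labelled NLP lay at most at 0.81% of its level in the other library of the label. A small admixture is not excluded. NLP5 and NLP8 lay at 434.44 and 327.57 CPM in the libraries labelled NLP5 and NLP8 replicate 2, against at most 56.14 and 47.48 CPM in their controls. A wrong label and a wrong plasmid remain open, and no biological explanation was tested.

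In the authors' deposited table for NLP6, NLP1 had a log2 fold change of 9.33, beside 9.89 for NLP6 and -0.47 for NLP4. The authors' deposited table for NLP4 correlated with the library labelled NLP6 replicate 1 at r = 0.982 and with that labelled NLP4 replicate 1 at 0.601, and the table for NLP6 at 0.75 and 0.766. Across genes, the authors' deposited tables for NLP5 and NLP8 correlated more with the libraries labelled NLP8 replicate 2 (r = 0.991) and NLP5 replicate 2 (0.988) than with the mismatched library of their own label (0.843 and 0.84).

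The absence of called genes in the nitrate response of the septuple mutant was weighed against 2 technical explanations. A smaller response is not excluded. NIR1 lay at 43.8, 31.6 and 37.1 CPM in K and at 66, 54.4 and 79.5 CPM in N there. A larger spread between the septuple mutant libraries was examined with the 26 genes chosen in chl1-5. Their fold changes themselves were low there, with an interval of the median up to 0.17, below the interval of wild type from 1.4. That interval is over genes and does not measure the spread between libraries. Between N replicates the median of these genes had an SD of 0.1 in the septuple mutant and 0.17 in wild type. In this median a larger spread was not seen. It leaves out the spread of the K libraries and averages over genes, so a larger spread of single genes remains open. Across genes, septuple mutant K replicate 3 had r of 0.8828 and 0.8899 with K replicates 1 and 2, against 0.9059 to 0.9294 for wild-type pairs. The other septuple mutant pairs had r between 0.94 and 0.9491. Shallower libraries are excluded, since their median depth was 1.23 times that of wild type. The mutated NLP genes, which the design names, may explain the absence of called genes, and this remains a hypothesis because these tests used the same data.

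Seedling replicates differed more than protoplast replicates. Counting noise is excluded as the cause, since it made up 2.72% of the squared coefficient of variation of seedling genes at 10 to 100 CPM, against 33.4% in protoplasts. Few RNA molecules per library could neither be excluded nor shown. The extra variation fell with the mean CPM with a slope of -0.38, between the bounds set before the test, and -0.28 in protoplasts. Differences between the plants of each sample remain open, as untested.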

How the results depend on the processing

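The control pair as 2 samples, the fit without the 4 mismatched libraries, the crossed pairing of NLP4 with NLP6 and the likelihood ratio test of DESeq2 were chosen after seeing the data. For the changed counts below the cause was not tested. NLP1, NLP2, NLP3, NLP7 and NLP9 hold none of the 4 mismatched libraries, so leaving these out can change their counts only through what all groups share. The common biological coefficient of variation was 0.16 with and 0.09 without the 4. The median log2 fold change of the nitrate-induced genes was 0.8 and 0.77 with NLP1, and 1.05 and 1.1 with NLP7. A count is called changed when it moved by more than 1.5 times. Counts are given in the order wild type, septuple mutant and chl1-5 (nitrate), septuple mutant against wild type, chl1-5 against wild type and septuple mutant against chl1-5 (interactions), and septuple mutant and chl1-5 against wild type in K.

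RLE size factors left all 31 results tried within these limits, and so did no fold threshold for the nitrate set (2 results). DESeq2 called 497, 4, 141, 484, 35, 32, 810 and 2574 genes, 692 for NLP1, 901 for NLP3, 1321 for NLP4, 1466 for NLP6 and 5 for NLP4 against NLP6. Of the 154 and 59 genes called in wild type and in the first interaction it called 152 and 46 as well. The nitrate-induced genes higher with NLP1, 3, 4, 5, 6 and 8 were then 10, 10, 43, 42, 49 and 41, past the threshold for NLP1 and NLP3 too. Its likelihood ratio test of NLP1, 2, 3, 5, 8 and 9 called 4376 genes. Without a filter on low counts the numbers were 549, 12, 69, 443, 54, 28, 843 and 2457, and 1214 (NLP1), 1442 (NLP3), 2309 (NLP4), 3183 (NLP5), 2473 (NLP6), 2981 (NLP7), 154 (NLP4 against NLP6) and 5474 (joint test).

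Within the sets checked, same-numbered replicates did not vary together (r between -0.49 and 0.39 for wild type with the septuple mutant, and between -0.19 and 0.2 within chl1-5). Their numbers therefore do not pair the samples of these sets, and chl1-5 with wild type was not checked. With the replicate number as a block, 17 genes were called in chl1-5, 36, 1 and 4 in the interactions, 13 for chl1-5 in K, and 119, 217, 230 and 288 with NLP1, 3, 4 and 6. The nitrate-induced genes higher with NLP1, 2, 3, 4, 5, 6 and 8 were then 0, 24, 0, 6, 11, 10 and 11. With NLP4 and NLP6 paired across replicate numbers the block gave 0 genes.

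With only the libraries of the groups compared, 85 genes were called in wild type, 15 in chl1-5, 0 for chl1-5 against wild type in response, 281 and 41 in K, and 2943, 5761, 4611, 6, 188, 132, 3741, 0 and 6871 with NLP1 to NLP9. The nitrate-induced genes among them were 52, 82, 48, 0, 12, 10, 67, 0 and 75, with NLP4 and NLP8 no longer past the threshold and NLP1 and NLP3 now past it. Of the named genes 64% kept their call. With the control pair as 2 samples the counts were 1784, 5181, 1954, 1013, 3967, 4072 and 5699 for NLP1, 2, 3, 4, 5, 8 and 9, and the nitrate-induced genes 13, 66, 13, 52 and 52 for NLP1, 2, 3, 5 and 8, past the threshold for NLP1 and NLP3 too. Without the 4 mismatched libraries they were 2918, 5983, 3117, 4672, 3509, 1599, 4554, 4783 and 6382 for NLP1 to NLP9, 1953 for NLP4 against NLP6 and 7922 in the joint test, with 53, 83, 46, 74, 67, 55, 71, 54 and 73 nitrate-induced genes, past the threshold for NLP1 and NLP3 too. Of the 68 list tests called, 4 held with an estimated correlation.

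With each replicate left out in turn, 108 of 208 values stayed within the limits. The 208 include values without 1 library of the control for NLP1, 2, 3, 5, 8 and 9. Its libraries were counted as 1 sample, so leaving 1 out mainly lowers its depth and does not test this control. The counts ranged from 82 to 208, 0 to 0, 15 to 46, 32 to 163, 0 to 21, 3 to 9, 246 to 485 and 152 to 2537 in seedlings. For NLP1 to NLP9 they ranged from 61 to 284, 1290 to 2473, 104 to 508, 65 to 2642, 829 to 1903, 56 to 1892, 664 to 968, 896 to 1996 and 2064 to 3368, for NLP4 against NLP6 from 0 to 308 and for the joint test from 2316 to 3689. The nitrate-induced genes ranged from 0 to 2, 17 to 36, 0 to 4, 0 to 52, 13 to 21, 0 to 48, 16 to 27, 13 to 26 and 26 to 32. The medians of the genes chosen in chl1-5 ranged from 2.16 to 2.45 in wild type and 0.01 to 0.15 in the septuple mutant, and the share of named genes that kept their call from 5% (without replicate 1 of the control for NLP4 and 6) to 100%. A lone library is assumed to vary like the other groups.

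Among named genes 5 values reversed, all NLP transcripts whose level differed between control libraries or that the mismatched libraries brought in. NLP9 with NLP2 was 0.19 without replicate 2 and -2.52 without replicate 1 of the control for NLP1, 2, 3, 5, 8 and 9. NLP2 was 0.19 with NLP5 and 0.33 with NLP8 without its replicate 1, and -1.84 and -1.7 without its replicate 2. NLP1 with NLP4 was -0.17 without the library labelled NLP4 replicate 1, 10.32 without NLP4 replicate 2 and -0.19 without the 4 mismatched libraries. Depth limits genes of low count, since 0 counts in 1 library allow up to 0.532 CPM in protoplasts and 0.164 CPM in seedlings.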

Other observations

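The genes and lists in this part were chosen after their values were seen, and no explanation was tested for them.

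The loci beside NRT1.1 in the reference gene order were examined in chl1-5, which as background is a deletion allele. In K, ELP, 2 places before NRT1.1, lay at 1.79 ± 0.516 CPM against 923 ± 309 CPM in wild type (-9.01 ± 0.74, adjusted p = 6.98e-08). In N it lay between 1.77 and 40.2 CPM in chl1-5 against a mean of 1780 CPM in wild type, and it is 1 of the 26 genes called for nitrate in chl1-5 (3.19). AT1G12100, 1 place before, had 0 counts in all 6 chl1-5 libraries and was at least 20.4-fold lower (adjusted p = 0.0206). AT1G12080, 3 places before, and AT1G12120, 1 place after, had log2 fold changes of 0.71 ± 0.25 (adjusted p = 0.0807) and -0.16 ± 0.23 (adjusted p = 0.711). AT1G12130, 2 places after, also had 0 counts in all 6 chl1-5 libraries. It lay at only 0.216 ± 0.079 CPM in wild type in K and was not called (adjusted p = 0.182). In the septuple mutant ELP had -0.36 (adjusted p = 0.872).

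TSO2 lay at 12.1 CPM in the control for NLP1, 2, 3, 5, 8 and 9 and at 6.70 ± 0.571 CPM in that for NLP4 and 6, but at 526 ± 7.23 CPM in that for NLP7. AT3G27630 lay at 0.0505, 0 and 21.8 ± 2.95 CPM in the same controls. With the NLPs, TSO2 lay between 103 ± 3.56 (NLP2) and 781 ± 80.5 CPM (NLP7). Without the 4 mismatched libraries its log2 fold change was 3.05 to 5.65 with the NLPs other than NLP7, and 0.60 with NLP7.

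Touch, wounding and rapid stress genes were lower as a list with NLP2, 7 and 9 (adjusted p = 0.00294, 0.0238 and 0.00531) and under the labels NLP5, 6 and 8 (2.54e-05, 0.00232 and 5.47e-05), with adjusted p = 0.466 to 0.692 by an estimated correlation. In the fit without the 4 mismatched libraries NLP5, 6 and 8, from 1 library each, had adjusted p = 2.16e-05, 6.98e-05 and 6.98e-05 (0.307, 0.325 and 0.325 with an estimated correlation). TCH3, a calmodulin-like gene, fell by 1.02 ± 0.12 under the label NLP8 (adjusted p = 0.000212), and the jasmonate repressor gene JAZ8 by 1.58 ± 0.27 with NLP9 (adjusted p = 0.00108). Heat shock genes were higher as a list with NLP1, 2, 3 and 9 (adjusted p = 0.00375, 0.00232, 0.0238 and 0.0105) and under the labels NLP5 and 8 (0.0148 and 0.0299), which share a control, with adjusted p = 0.466 to 0.555 by an estimated correlation. In that fit the list was called with NLP8 (adjusted p = 0.0336, and 0.48 with an estimated correlation) and not with NLP5 (0.125 and 0.674). The heat shock factor HSFA2 rose by 1.54 ± 0.24 with NLP2 (adjusted p = 0.00101) and 1.48 ± 0.23 with NLP9 (adjusted p = 0.000605).

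BT2, which rose with nitrate in seedlings, was called with none of the NLPs by edgeR with all libraries (adjusted p between 0.117 and 0.984, and 0.136 in the joint test). In the fit without the 4 mismatched libraries it was higher with NLP7 (0.81, adjusted p = 0.000158). It was lower with NLP1, 2, 3 and 9 (-0.51, -1.19, -1.78 and -0.98, adjusted p at most 0.0404). From 1 library each, its log2 fold change was 1.28 with NLP6 and -1.16 with NLP8. BT2 lay at 180 CPM in the control for NLP1, 2, 3, 5, 8 and 9, and at 79.5 and 58.7 CPM in that for NLP7. With NLP1 it lay at 143 and 114 CPM and with NLP7 at 123 and 113 CPM. The level of the control therefore enters these opposite signs.

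NLP3 lay at 17.92 CPM in NLP4 replicate 2 and 17.21 CPM in the library labelled NLP6 replicate 1, and at 0.16 CPM or less in the control for NLP4 and 6.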
